A study of Mus musculus with 8 samples.

How the data were processed

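Messenger RNA of mouse liver was measured in 8 libraries made from poly(A)-selected RNA. The libraries form 2 arms of 4, and each arm holds 2 control libraries, called NC in the labels, and 2 libraries from mice given a short hairpin RNA against Thbs2 (shThbs2) in an adeno-associated virus of serotype 6. The vectors of the arms are named CMV and αSMA. The CMV libraries were sequenced on the HiSeq2500 at Biomarker Technologies and the αSMA libraries on the DNBSEQ-T7 at Frasergen, so vector, platform and provider cannot be told apart between arms.

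The authors deposited 1 table of FPKM values per arm (fragments per kilobase of transcript, scaled by the mapped fragments of the library), and the tables were normalised separately. Per the submitters' processing notes, HISAT, Cufflinks, HISAT2 2.1.0 and Bowtie2 2.3.5 were used with genome build GRCm38. Which tool made which table is not given in the sources used here. The tables hold no read counts, so the depth of each library is unknown and no counting interval is given. In the αSMA controls, nonzero values under 0.2 FPKM take 19 distinct values, because they are rounded to 2 decimals. Of 3069 features with such values in both controls, 11.4% fall in the fullest narrow step of the ratio between the controls. In the CMV controls the fullest step of that ratio holds 1.23% of 1304 features.

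The CMV table lists 24662 features, of which 22036 carry an Ensembl identifier and 2626 are unnamed transcripts. Its 27 gene symbols that a spreadsheet had turned into dates were replaced through their Ensembl identifiers. The αSMA table lists 27261 features, 26290 with an Ensembl identifier. GENCODE M21 gave biotypes, coordinates, transcript lengths and GC content, and 17593 identifiers are in both tables. Features at 0 in all 4 libraries number 6493 in the CMV table and 1942 in the αSMA table.

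Each arm was analysed alone on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided), without a replicate block. Features with a mean of at least 1 FPKM over the 4 libraries of the arm were tested, which left 10916 in the CMV arm (10500 protein coding) and 13012 in the αSMA arm (11300 protein coding). Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Each arm has 2 residual degrees of freedom. The effects of the arms were compared in 1 limma model of all 8 libraries with a mean per group, over the 10245 genes tested in both arms. Levels were not tested across tables, and shares of the FPKM sum are given for both arms only as description. For Thbs2 an exact permutation test was added, two-sided, within each arm and stratified over both arms. Thbs2 lies under the filter in the CMV arm and was taken there from the limma model without a filter, as was the difference of its effect between arms, over 15587 genes.

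The series text speaks of separate mice, and the libraries were taken as 1 animal each. If they were not, the p-values measure only the spread between these libraries.

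Before the data were examined, 41 gene lists were fixed, covering matrix, liver cell types, signalling, metabolism, stress, sex-biased expression and RNA from other tissues. Lists with at least 3 tested members were tested with camera from limma, which compares a list with all other genes, with a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move in 1 direction on balance, were run beside it. With an estimated correlation camera tests on the residual degrees of freedom, 2 in each arm. A list can then fail through these few degrees of freedom, whatever its correlation. Members past the threshold were counted over all genes and adjusted over the list alone. A further list of 51 nuclear-encoded respiratory chain genes was written after the data were seen and tested on its own in the αSMA arm.

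Named genes were chosen by a rule fixed at the same time. Thbs2 and 8 fibrosis reference genes are given in both arms whatever their p. Of the genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in 1 group, the 12 with the greatest change in each direction are named, leaving out predicted and unnamed models. Where fewer than 5 genes passed in a direction, the 8 with the smallest p are named as not passing. List examples are among the 4 members with the smallest p, and the alternatives were run for the first 2 of these. Between arms, genes called in both and the 8 with the smallest adjusted p for the difference are named. Some genes that these rules pick are not reported here.

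The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling each library of an arm to the same FPKM sum, median centring, quantile normalization, robust empirical Bayes, a replicate block, the joint model, a threshold on unadjusted p with a 2-fold change, and leaving out each library in turn. In the last case the lone library of a group was assumed to vary like the other group. Rescaling over nuclear protein-coding genes and testing protein-coding genes alone were chosen after seeing the data. Length and GC trends were removed per library with a loess span of 0.3, together and, after seeing the data, singly.

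The models were tested on simulated data with the spread of each arm and 200 changed genes. In the CMV arm limma recovered 52% of 2-fold and 89% of 4-fold changes, with 7 false calls among 148. In the αSMA arm it recovered 2% and 39%, with 2 false calls among 43, and 0 calls had the wrong sign in either arm. The simulation changed 200 of 13012 αSMA genes, whereas limma called 4691 in the data. The adjusted p depends on the share of changed genes, so these αSMA rates do not carry over to the data. A planted list was recovered in both arms and 0 lists without a change were called. The simulated genes varied independently of each other. In the data the estimated correlation of male-biased genes was 0.62 in the CMV arm and 0.91 in the αSMA arm. The 0 false list calls therefore do not bear on lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All value columns of both tables were used.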

Results

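Liver RNA was profiled in 8 libraries in 4 groups of 2. In the CMV arm, named for a viral promoter active in many cell types, control replicates 1 and 2 stood against shThbs2 replicates 1 and 2. In the αSMA arm, named for the smooth muscle actin that activated hepatic stellate cells express, control replicates 3 and 4 stood against shThbs2 replicates 3 and 4. The values are FPKM, the depth is unknown, and between 10769 and 10996 features per CMV library and between 12528 and 12852 per αSMA library reached 1 FPKM. Libraries of the same group correlated with r between 0.974 and 0.988 across genes, which are not independent replicates. The FPKM sums were 504227 and 491931 in the CMV controls and 514641 and 503000 in the CMV knockdown. They were 941530 and 924060 in the controls and 1253740 and 1225210 in the knockdown of the αSMA arm, so this sum moved with the group. Transcripts encoded by the mitochondrial genome made up 12.2% and 12.1% of the sum in the αSMA controls and 23.1% and 24.6% in the αSMA knockdown. In the CMV arm they made up 13.3% and 13.9% in the controls and 14.8% and 15.8% in the knockdown. The αSMA table also lists 7 nuclear copies of mitochondrial genes that are absent from the CMV table, so the shares of the arms are not alike.

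The first question is whether Thbs2 RNA itself was lower. Thbs2 (ENSMUSG00000023885, chromosome 17, 14665500 to 14694235, minus strand, GRCm38) encodes thrombospondin-2, a secreted matricellular glycoprotein. In the CMV arm it measured 1.27 and 0.922 FPKM in the controls and 0.695 and 0.614 FPKM in the knockdown. The means were 1.10 ± 0.249 and 0.654 ± 0.0576 FPKM (SD, n = 2), which is 40.4% lower. The αSMA controls measured 1.37 and 1.47 FPKM and the knockdown 0.85 and 1.14 FPKM, or 1.42 ± 0.0707 and 0.995 ± 0.205 FPKM (SD, n = 2), which is 29.9% lower. The Thbs2 groups did not overlap in either arm, and the exact permutation p was 0.333 in each, the smallest that 2 libraries against 2 allow. Groups also did not overlap for 42.0% of all tested CMV genes and 74.9% of αSMA genes, against 33.3% by chance. Stratified over both arms, the exact permutation p was 0.0556, the smallest that 36 assignments allow. The limma log2 change was −0.34 (SE 0.13, 95% confidence interval −0.70 to 0.03, adjusted p = 0.60) in the CMV arm. The αSMA change was −0.28 (SE 0.18, 95% confidence interval −0.75 to 0.18, adjusted p = 0.269), and neither passed. The median change of all tested αSMA genes was itself −0.16, and the αSMA change of Thbs2 was smaller with median centring, as given below. The Thbs2 effects of the arms differed by 0.06 (SE 0.18, limma adjusted p = 0.856 over the 15587 genes of the joint model without a filter). These log2 changes are of FPKM + 1. The added 1 shrinks them for a gene near 1 FPKM, so they understate the falls of 40.4% and 29.9%. The FPKM sums of the tables differ, so the shrinkage need not be alike in both arms.

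Among the other thrombospondins, Thbs1, whose product activates latent TGF-β, fell in the αSMA arm from 16.7 ± 3.21 to 4.87 ± 3.87 FPKM (SD, n = 2; log2 change −1.75, limma adjusted p = 0.0418). Without a filter on low values that adjusted p was 0.130. Thbs3 in the αSMA arm had a log2 change of 0.75 (adjusted p = 0.0723). Of the 3 thrombospondins tested there, 0 rose and 1 fell over all genes, and 1 rose and 1 fell adjusted over the list alone, with a list mean of −0.43 (camera adjusted p = 0.986). In the CMV arm 0 thrombospondins passed the filter. Without it the limma log2 change there was −0.39 for Thbs1 (adjusted p = 0.621), 0.16 for Thbs3 and −0.13 for Thbs4, with 0 past the threshold.

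The fibrosis reference genes address whether matrix and stellate cell activation fell with the hairpin. The labels name no injury model and no uninjured liver was analysed here, so each value is set only against the controls of its arm. In the CMV arm the mean of Col1a1, a chain of type I collagen, was 10.6 FPKM in the controls and 7.23 FPKM in the knockdown (log2 change −0.51, limma adjusted p = 0.445), and Col1a2 measured 13.3 and 9.07 FPKM (−0.50, adjusted p = 0.385). Col3a1, the chain of type III collagen, measured 21.7 and 14.7 FPKM (−0.53, adjusted p = 0.309), and Acta2, which encodes αSMA, 4.55 and 1.92 FPKM (−0.91, adjusted p = 0.293). Des (−0.31, adjusted p = 0.563), Pdgfrb (−0.22, adjusted p = 0.707), Timp1 (−0.38, adjusted p = 0.595 without a filter) and Tgfb1 (−0.04, adjusted p = 0.944) did not pass either. Without control replicate 1, Acta2 passed (−1.14, adjusted p = 0.0435). Acta2 fell in the αSMA arm from 15.7 ± 1.92 to 8.39 ± 0.0636 FPKM (log2 change −0.83, limma adjusted p = 0.0170) and Timp1, an inhibitor of matrix metalloproteinases, from 12.6 ± 2.27 to 3.79 ± 1.82 FPKM (−1.55, adjusted p = 0.0187; SD, n = 2). Tgfb1, the main profibrotic cytokine, fell from 10.8 ± 1.07 to 4.60 ± 0.460 FPKM (−1.08, adjusted p = 0.0110), and Pdgfrb, the PDGF receptor of stellate cells, from 5.87 ± 0.0283 to 3.67 ± 0.403 FPKM (−0.56, adjusted p = 0.0394). Col1a1 (10.8 and 4.93 FPKM, −0.94, adjusted p = 0.0644), Col1a2 (−0.78, adjusted p = 0.0849), Col3a1 (−0.63, adjusted p = 0.116) and Des (−0.28, adjusted p = 0.220) did not pass. They did with rescaling to the same FPKM sum, where the adjusted p was 0.0206 for Col1a1, 0.0234 for Col1a2, 0.0266 for Col3a1 and 0.0333 for Des. In the joint model the collagens passed (0.0196, 0.0263 and 0.0387), and with a replicate block Col1a1 (0.0326) and Col1a2 (0.0379). Over all alternatives the adjusted p ranged from 0.0196 to 0.262 for Col1a1, 0.0234 to 0.369 for Col1a2, 0.0266 to 0.473 for Col3a1 and 0.0333 to 0.776 for Des. The 4 αSMA calls were lost without control replicate 3, control replicate 4 or knockdown replicate 3, where the adjusted p of Tgfb1 was 0.113, 0.119 and 0.0545, that of Acta2 0.113, 0.159 and 0.0669, that of Timp1 0.117, 0.157 and 0.0615 and that of Pdgfrb 0.192, 0.211 and 0.106. Without a filter Acta2 (0.0516), Timp1 (0.0718) and Pdgfrb (0.0960) were lost, and Pdgfrb also without knockdown replicate 4 (0.0528), with median centring (0.0892), with quantile normalization (0.0857), with a replicate block (0.0538) and with rescaling over nuclear genes (0.0552).

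**Figure D1:**
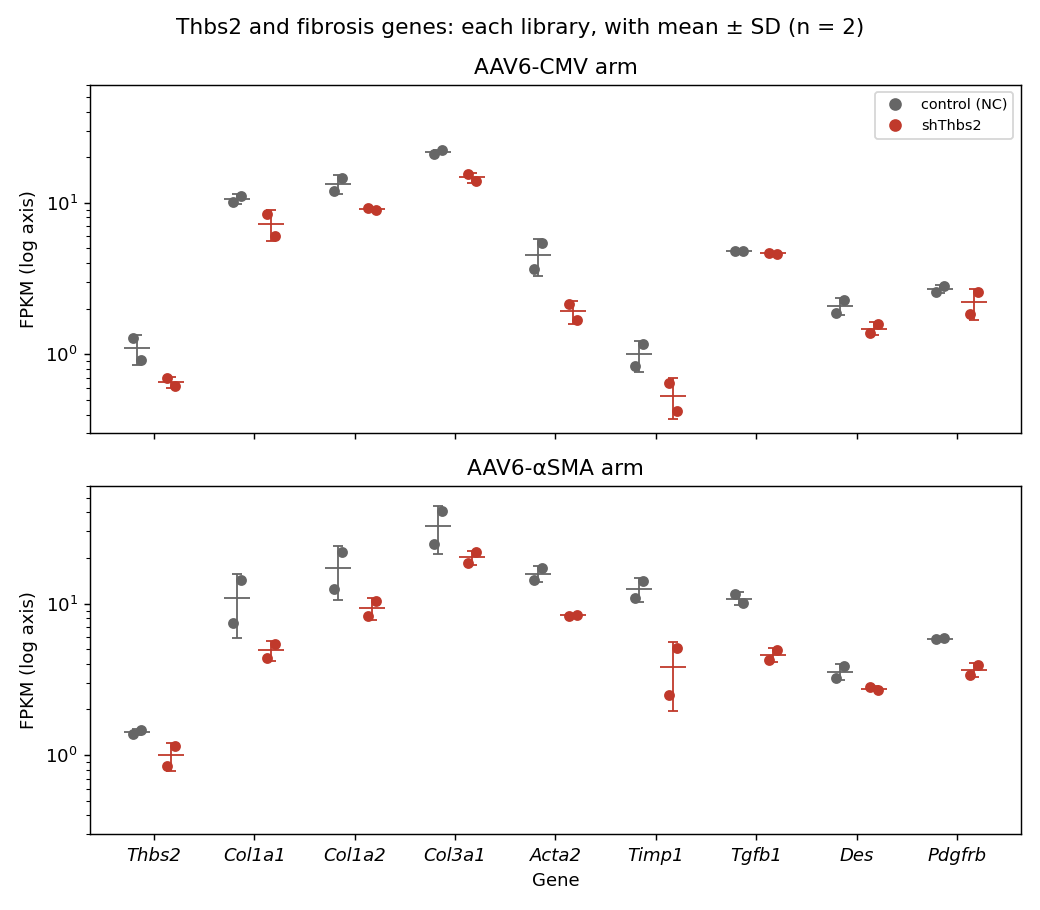
FPKM of Thbs2 and the fibrosis reference genes in each library, on log axes, with points for libraries (grey controls, red shThbs2) and bars for the mean ± SD (n = 2). Thbs2 lies between 0.614 and 1.27 FPKM in the CMV arm and between 0.85 and 1.47 FPKM in the αSMA arm, with every knockdown library under both controls of its arm.

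In the CMV arm 2 genes rose. Angptl4 (ENSMUSG00000002289, chromosome 17, 33773750 to 33781830, minus strand), which encodes a secreted inhibitor of lipoprotein lipase and is a target of the lipid sensor PPARα, rose from 10.3 ± 0.787 to 44.5 ± 2.97 FPKM (SD, n = 2; log2 change 2.01, SE 0.14, limma adjusted p = 0.0278). Mup15 (ENSMUSG00000096674, chromosome 4, 61435790 to 61439743, minus strand), a major urinary protein gene, rose from 0.297 ± 0.0515 to 64.8 ± 19.2 FPKM (SD, n = 2; log2 change 5.63, SE 0.22, limma adjusted p = 0.00202). Mup genes are near-identical in sequence, so which of them the values belong to is uncertain. Limma tested 10916 genes and 0 fell, while at an unadjusted p under 0.05 there were 1113 (625 higher, 488 lower), where 546 would pass by chance. The groups did not overlap for 42.0% of genes, against 33.3% by chance.

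Of the CMV genes with the smallest p that did not pass, Akr1c18, which inactivates progesterone, had means of 19.9 and 1.22 FPKM (log2 change −3.29, limma adjusted p = 0.0853), Lpl, lipoprotein lipase, 58.7 and 23.1 FPKM (−1.31, adjusted p = 0.0926) and Lcn2, a marker of liver injury, 292 and 121 FPKM (−1.27, adjusted p = 0.0947). Lower values were also measured for Egr1 (−2.24, adjusted p = 0.0947), Cyp17a1 (−1.95, adjusted p = 0.0947), Slc1a4 (−1.22, adjusted p = 0.0947), Angptl8 (−1.55, adjusted p = 0.102) and Rdh9 (−2.04, adjusted p = 0.133). Higher values were measured for Cyp4a12b (1.87, adjusted p = 0.0853), Mup1 (3.49, adjusted p = 0.0926), Cyp2a5 (1.95, adjusted p = 0.0947), Herpud1 (1.11, adjusted p = 0.0947), Hspb1 (1.65, adjusted p = 0.137), Mup13 (2.35, adjusted p = 0.137), Serpina7 (1.83, adjusted p = 0.137) and Slc25a33 (1.11, adjusted p = 0.137). The Cyp2a, Cyp4a12 and Mup families hold close paralogs, so these values are uncertain. Angptl4 and Mup15 stayed past the threshold when any 1 library was left out, with adjusted p up to 0.0418 and 0.000301. The number of genes past the threshold became 152 without control replicate 1, 131 without control replicate 2, 10 without knockdown replicate 1 and 18 without knockdown replicate 2. Without a filter limma called 0 genes, with Angptl4 at an adjusted p of 0.283 and Mup15 at 0.168, and in the joint model Mup15 did not pass (adjusted p = 0.0915).

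Lists of matrix, contractile, stellate, and monocyte, neutrophil and scar macrophage genes of the CMV arm were lower by camera with the preset correlation. None of their genes passed limma singly. The Kupffer cell, the T, NK and B cell, and the TLR4 and NF-kB lists did not pass camera, as given below. Of 23 collagens and matrix proteins 1 was higher, with a list mean of −0.33 (camera adjusted p = 1.57e-08; adjusted p = 0.379 with an estimated correlation), including Postn (−0.62) and Sparc (−0.49). Of 12 contractile myofibroblast genes 0 were higher, with a mean of −0.52 (camera adjusted p = 1.57e-08; adjusted p = 0.379 with an estimated correlation), among them Tagln2 (−0.73), Lgals1 (−0.76) and Myl9 (−0.68). Of 17 stellate cell markers 3 were higher, with a mean of −0.26 (camera adjusted p = 0.000243; adjusted p = 0.379 with an estimated correlation), including Reln (−0.87). Of 16 matrix crosslinking and remodelling genes 3 were higher, with a mean of −0.28 (camera adjusted p = 0.000308), with Pcolce at −0.77 and Mmp14 at −0.79, and of 16 TGF-β signalling genes 3 were higher, with a mean of −0.25 (camera adjusted p = 0.00454), with Inhba at −1.24. With an estimated correlation the adjusted p was 0.379 for both. Of 12 markers of monocytes, neutrophils and scar macrophages 0 were higher, with a mean of −0.55 (camera adjusted p = 1.30e-06; adjusted p = 0.379 with an estimated correlation), among them Chil3 (−0.93), Ccr2 (−0.58), S100a9 (−0.77) and Spp1 (−0.75). Of 4 cholangiocyte markers, which also hold Spp1, 0 were higher, with a mean of −0.41 (camera adjusted p = 0.00372; adjusted p = 0.379 with an estimated correlation). Of 14 liver endothelial markers 4 were higher, with a mean of −0.12 (camera adjusted p = 0.0449; adjusted p = 0.648 with an estimated correlation). They lost the call without control replicate 2 (0.429), knockdown replicate 1 (0.145) or knockdown replicate 2 (0.0586), without a filter and in the joint model. Without control replicate 1 the mean was −0.32 for monocytes and neutrophils and −0.21 for endothelial markers, and without control replicate 2 it was −0.35 for contractile and −0.021 for endothelial genes. The TGF-β mean was −0.38 with a pseudocount of 0.1 and −0.16 at a mean of 5 FPKM, and the cholangiocyte mean −0.25 without a filter. Over all genes limma called 0 members of these 8 lists. Adjusted over the list alone, 5 contractile, 5 monocyte and neutrophil, 2 crosslinking, 1 stellate, 1 TGF-β and 1 cholangiocyte gene fell, and 0 collagens and 0 endothelial genes. At an unadjusted p under 0.05 limma found the 488 lower genes given above.

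The male-biased list and 4 metabolic lists of the CMV arm passed camera with the preset correlation, in both directions. All 12 male-biased liver genes were higher, with a mean of 1.25 (camera adjusted p = 3.16e-08; adjusted p = 0.379 with an estimated correlation), 8 of them past the threshold adjusted over the list alone, with the fatty acid elongase Elovl3 at 2.95, Cyp7b1 at 1.59 and Mup20 at 0.82. Of 22 cholesterol synthesis genes 2 were higher, with a mean of −0.32 (camera adjusted p = 8.18e-07), including Dhcr7 (−1.06). Of 18 fatty acid synthesis genes 5 were higher, with a mean of −0.26 (camera adjusted p = 0.000243), including the lipogenic regulator Srebf1 (−1.18) and Pnpla3 (−0.99). Adjusted over the list alone 1 cholesterol gene fell, and 1 fatty acid synthesis gene rose and 3 fell. With an estimated correlation the adjusted p was 0.379 for both lists, and the fatty acid synthesis call was lost without control replicate 1 (0.0559). Of 24 fatty acid oxidation and PPARα genes 18 were higher, with a mean of 0.26 (camera adjusted p = 0.00454; adjusted p = 0.578 with an estimated correlation), 1 past the threshold over all genes and 4 adjusted over the list alone. These included Angptl4, Acaa1b (1.02) and the hormone gene Fgf21 (1.53), and the list call was lost without control replicate 1 (mean 0.10, adjusted p = 0.420). Without control replicate 2 the mean was 0.41 for fatty acid oxidation, −0.18 for cholesterol and 0.79 for male-biased genes. Of 18 bile acid genes 15 were higher, with a mean of 0.44 (camera adjusted p = 0.000631; adjusted p = 0.379 with an estimated correlation; 0 adjusted over the list alone), including the exporter Abcc4 (1.44), Cyp8b1 (0.71) and Slco1b2 (0.55).

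The CMV arm had 7 other lists past the camera threshold with the preset correlation. Of 24 xenobiotic metabolism genes 12 were higher, with a mean of −0.25 and a median of −0.05 (camera adjusted p = 0.0396; adjusted p = 0.379 with an estimated correlation), with Cyp2a5 at 1.95, Gstm3 at −1.85, Gstm2 at −0.92 and Nqo1 at −0.72, and 2 higher and 6 lower adjusted over the list alone. Of 19 urea cycle and amino acid genes 15 were higher, with a mean of 0.17 (camera adjusted p = 0.0370; adjusted p = 0.658 with an estimated correlation), with Tat at 0.68 and Cth at 0.58, and 1 higher adjusted over the list alone. Both calls were lost with median centring, in the joint model and without control replicate 2 (0.111 and 0.655). The xenobiotic call was also lost without knockdown replicate 1 (0.0859) or a filter, and the urea call without knockdown replicate 2 (0.569), with quantile normalization and at a mean of 5 FPKM. The xenobiotic mean was −0.38 without control replicate 1 and −0.12 without control replicate 2. The urea mean was 0.095 without control replicate 2, 0.26 without knockdown replicate 1, 0.084 without knockdown replicate 2 and 0.054 with quantile normalization. Of 12 p53 targets 11 were higher, with a mean of 0.42 (camera adjusted p = 0.00115; adjusted p = 0.379 with an estimated correlation), including the cell cycle inhibitor Cdkn1a (1.01) and Trp53inp1 (1.04), and 2 rose adjusted over the list alone. Of 24 cell cycle genes 5 were higher, with a mean of −0.21 (camera adjusted p = 0.00215; adjusted p = 0.404 with an estimated correlation; 0 adjusted over the list alone), with Ccnd1 at −1.21 and Mki67 at −0.67. That call was lost without knockdown replicate 1 (0.0608), and the mean was −0.32 without control replicate 1 and −0.098 without control replicate 2. Of 13 immediate early genes 2 were higher, with a mean of −0.43 (camera adjusted p = 0.000243; adjusted p = 0.379 with an estimated correlation), with Egr1 and Fos (−0.79) lower and 1 past the threshold adjusted over the list alone. All 13 mitochondrially encoded genes were higher, with a mean of 0.21 (camera adjusted p = 0.000631; adjusted p = 0.379 with an estimated correlation). Of 25 ribosomal protein genes 24 were higher, with a mean of 0.31 (camera adjusted p = 1.33e-07; adjusted p = 0.384 with an estimated correlation), and 0 of either list passed adjusted over the list alone. The ribosomal mean was 0.19 with quantile normalization. In all, camera called 20 lists with the preset correlation and 0 with an estimated one, which tests on 2 residual degrees of freedom. Fry called 0.

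The remaining lists of the CMV arm did not pass camera. Acute phase genes had a mean of 0.42 (camera adjusted p = 0.0541), with Saa1 at 2.48 and Saa2 at 3.11, a pair of near-identical genes, and 3 higher and 1 lower adjusted over the list alone. That list passed with rescaling to the same FPKM sum (0.0411) and over nuclear genes (0.0393), and focal adhesion with median centring (0.0410) and quantile normalization (0.0324). With an estimated correlation the adjusted p in these 4 settings was 0.599, 0.575, 0.550 and 0.574. Female-biased genes had a mean of −0.33 (camera adjusted p = 0.0541; 2 lower adjusted over the list alone), with Cyp2b9 at −2.29. The camera adjusted p was 0.0517 for focal adhesion (mean −0.10), 0.106 for blood cells (−1.03), 0.167 for T, NK and B cells (−0.33), 0.266 for ER stress (0.30), 0.304 for Kupffer cells (−0.07), 0.432 for the circadian clock (−0.05), 0.752 for antigen presentation (−0.04) and 0.830 for both TLR4 and NF-kB (0.11) and Y-linked genes (−0.01). For blood cells, Hba-a1 measured 710 FPKM in control replicate 1 and 144 FPKM in control replicate 2. It was 0.860 for periportal (0.12) and 0.903 for pericentral hepatocytes (0.09). Glycolysis and gluconeogenesis (mean 0.02, median −0.10, camera down, adjusted p = 0.459) and the interferon response (mean 0.02, median 0.05, camera down, adjusted p = 0.885) differed in sign between measures. So did hepatocyte identity (mean 0.01, camera down, adjusted p = 0.860), and these 3 and oxidative stress (adjusted p = 0.903) changed the sign of their mean with the scaling. Among members, Pck1, the gluconeogenic enzyme, was at 0.90. Of the contaminant lists, 1 pancreas gene (Cela1, −0.01), 0 skeletal muscle and 0 adipose or mesothelium genes were abundant enough to test.

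In the αSMA arm Cyp7a1 (chromosome 4, 6265612 to 6275633, minus strand), the rate-limiting enzyme of bile acid synthesis, rose from 0.075 ± 0.0212 to 11.5 ± 1.20 FPKM (SD, n = 2; log2 change 3.54, limma adjusted p = 0.00175). Bhmt, which remethylates homocysteine, rose from 57.0 ± 50.9 to 1765 ± 183 FPKM (SD, n = 2; log2 change 5.28, adjusted p = 0.00869). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, fell from 717 ± 32.1 to 67.8 ± 15.2 FPKM (SD, n = 2; log2 change −3.40, adjusted p = 0.00293).

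Of the other genes with the greatest rise in the αSMA arm, Cyp2a4, a steroid hydroxylase with close paralogs, was 23.1 and 2.02 FPKM in the controls and averaged 1214 FPKM in the knockdown (log2 change 7.12, limma adjusted p = 0.00927). The uridine phosphorylase Upp2 rose from 1.46 to 105 FPKM (5.33, adjusted p = 0.00413) and Serpina6, which encodes the corticosteroid carrier of plasma, from 8.85 to 186 FPKM (4.17, adjusted p = 0.00563). Thrsp, a lipogenic gene, rose from a mean of 6.19 FPKM to 457 and 67.0 FPKM in the knockdown libraries (4.64, adjusted p = 0.0175). Hamp2, a hepcidin gene, rose from 22.1 to 265 FPKM (3.82, adjusted p = 0.0134) and Hjv, the hemojuvelin co-receptor that controls hepcidin, from 2.19 to 40.5 FPKM (3.68, adjusted p = 0.00572). Cyp2b9 (4.23, adjusted p = 0.0173), Cyp2a22 (4.26, adjusted p = 0.00563), Plscr2 (3.67, adjusted p = 0.00143) and Akr1b7 (3.56, adjusted p = 0.00518) complete the 12.

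Of the genes with the greatest fall in the αSMA arm, Npy, a neuropeptide, fell from 100.2 ± 9.0 FPKM to 0 and 0.94 FPKM (log2 change −6.18, limma adjusted p = 0.00241) and the angiogenic factor Pgf from 31.3 to 0.15 FPKM (−4.81, adjusted p = 0.00101). Sprr1a, a cornified envelope protein, fell from 1154 to 51.1 FPKM (−4.46, adjusted p = 0.00175). Its neighbour Sprr1b measured 26.8 and 42.8 FPKM in the controls and is listed at 0 in both knockdown libraries (adjusted p = 0.00187). The neutrophil chemokine Cxcl2 fell from 18.3 to 0.85 FPKM (−3.35, adjusted p = 0.00635) and the hydrolase Abhd2 from 77.2 to 6.36 FPKM (−3.44, adjusted p = 0.00352). The zinc transporter Slc30a4 (−3.26, adjusted p = 0.0150), Arhgap22 (−3.21, adjusted p = 0.00241) and the U3 RNA copies Rnu3b1 (−5.73, adjusted p = 0.00974) and Rnu3b3 (−5.68, adjusted p = 0.010) fell too. The Rnu3b copies are near-identical, short and not polyadenylated, so their values are uncertain.

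Limma called 4691 of 13012 αSMA genes, 1729 higher and 2962 lower, of which 864 and 1100 changed at least 2-fold. At an unadjusted p under 0.05 there were 6491, where 651 would pass by chance, and the groups did not overlap for 74.9% of genes, against 33.3% by chance. The median log2 change of all genes was −0.16. It was −0.50 with each library rescaled to the same FPKM sum and 0.05 with median centring, so the share of calls that were higher, 36.9%, became 13.8% and 57.6%. The number of calls was 53 without control replicate 3, 46 without control replicate 4, 1111 without knockdown replicate 3 and 4137 without knockdown replicate 4, and 1843 without a filter. Pgf, Sprr1a and Sprr1b stayed past the threshold whichever library was left out, and of 51 genes that the rules for named genes picked and limma called, 9, 4, 35 and 47 did so in the same order of libraries.

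Camera with the preset correlation called 6 lists higher in the αSMA arm, 0 of which passed with an estimated one. The estimated test has 2 residual degrees of freedom, so failing it does not show that correlated genes made the call. For the urea cycle list the estimated correlation was −0.03. Its unadjusted camera p was still 1.55e-06 with the preset correlation and 0.035 with the estimated one. Of 18 bile acid genes 12 rose and 0 fell, over all genes and adjusted over the list alone, with a mean of 1.36 (camera adjusted p = 4.58e-06; adjusted p = 0.872 with an estimated correlation). They include Slco1b2 (2.20, limma adjusted p = 0.00437), Abcc4 (2.73, 0.00518) and Baat (2.45, 0.00644). Of 19 urea cycle and amino acid genes 11 rose and 0 fell by both counts, with a mean of 1.09 (camera adjusted p = 2.02e-05; adjusted p = 0.872 with an estimated correlation), among them Cth (2.68, limma adjusted p = 0.00352) and Asl (1.75, 0.00765). Of 24 xenobiotic metabolism genes 11 rose and 3 fell, and 13 and 4 adjusted over the list alone, with a mean of 1.07 (camera adjusted p = 0.000671; adjusted p = 0.872 with an estimated correlation). The nuclear receptor Nr1i3 (2.25, limma adjusted p = 0.00563), its target Cyp2b10 (2.3, 0.00351) and Gstm2 (3.02, 0.00241) were among them. Of 18 fatty acid synthesis genes 6 rose and 1 fell by both counts, with a mean of 1.02 (camera adjusted p = 0.00313; adjusted p = 0.872 with an estimated correlation). Acaca, acetyl-CoA carboxylase (1.53, limma adjusted p = 0.00735), and the glucose sensor Mlxipl (2.12, 0.0191) rose and Dgat2 fell (−1.11, 0.0160). That list call was lost without knockdown replicate 3 (mean 0.46, adjusted p = 0.127), and the mean was 1.58 without knockdown replicate 4. Of 12 pericentral hepatocyte genes 7 rose and 0 fell by both counts, with a mean of 0.44 (camera adjusted p = 0.0154; adjusted p = 0.872 with an estimated correlation), including Cyp27a1 (1.00, limma adjusted p = 0.0274) and Cyp2e1 (0.86, 0.0275). With rescaling to the same FPKM sum the pericentral mean was 0.075, with 0 genes past the limma threshold. The call was lost with quantile normalization (0.0612, with 4 genes called), at a mean of 5 FPKM (0.0701) and without knockdown replicate 3 (mean 0.28, adjusted p = 0.126). All 13 mitochondrially encoded genes rose by both counts, with a mean of 1.41 (camera adjusted p = 7.76e-08; adjusted p = 0.872 with an estimated correlation), including mt-Atp6 (1.98, limma adjusted p = 0.00609), mt-Co3 (2.24, 0.00703) and mt-Nd3 (1.67, 0.00644).

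Camera with the preset correlation called 7 lists lower in the αSMA arm, and 0 of them passed with an estimated one. Of 21 TLR4 and NF-kB genes 0 rose and 11 fell, and 15 fell adjusted over the list alone, with a mean of −0.91 (camera adjusted p = 0.000671; adjusted p = 0.872 with an estimated correlation). The monocyte chemokine Ccl2 (−1.81, limma adjusted p = 0.00543), Nfkb2 (−1.50, 0.00702) and the NF-kB inhibitor Tnfaip3 (−1.98, 0.00703) were among them. Of 18 focal adhesion genes 0 rose and 8 fell, and 11 fell adjusted over the list alone, with a mean of −0.74 (camera adjusted p = 0.0128; adjusted p = 0.872 with an estimated correlation), including vinculin (Vcl, −2.92, limma adjusted p = 0.00546), Actn1 (−1.36, 0.00704) and the integrin chain Itgb1 (−1.43, 0.0105). Of 21 acute phase genes 2 rose and 10 fell, and 2 and 13 adjusted over the list alone, with a mean of −0.88 (camera adjusted p = 0.0154; adjusted p = 0.872 with an estimated correlation). Saa1 fell from 712 to 77.8 FPKM (−3.18, limma adjusted p = 0.00187), a value shared with its near-identical neighbour Saa2 (−2.88, 0.00516), and the interleukin-1 antagonist Il1rn (−2.96, 0.00563) and fibrinogen Fga (−2.22, 0.00688) fell. Of 15 markers of monocytes, neutrophils and scar macrophages 0 rose and 8 fell by both counts, with a mean of −0.98 (camera adjusted p = 0.0154; adjusted p = 0.872 with an estimated correlation), among them Itgam (−1.65, limma adjusted p = 0.00728), Chil3 (−2.86, 0.00881) and Ccr2 (−1.14, 0.0111). Of 20 matrix crosslinking and remodelling genes 0 rose and 7 fell by both counts, with a mean of −0.77 (camera adjusted p = 0.0286; adjusted p = 0.872 with an estimated correlation), including the collagenases Mmp13 (−2.54, limma adjusted p = 0.00745) and Mmp14 (−1.75, 0.0154) and the macrophage elastase Mmp12 (−2.85, 0.0178). Of 22 TGF-β signalling genes 0 rose and 11 fell by both counts, with a mean of −0.71 (camera adjusted p = 0.0396; adjusted p = 0.876 with an estimated correlation), including the receptor Tgfbr2 (−1.10, limma adjusted p = 0.00881) and the target Ccn1 (−1.59, 0.00881). Of 15 immediate early genes 1 rose and 7 fell by both counts, with a mean of −0.91 (camera adjusted p = 0.0396; adjusted p = 0.872 with an estimated correlation), including Jun (−1.41, limma adjusted p = 0.00930) and Ier3 (−2.86, 0.00703).

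Part of these αSMA calls depended on the scaling or on 1 library. With rescaling to the same FPKM sum limma called 8 bile acid genes higher and 1 lower, 9 and 2 urea cycle genes, 9 and 4 xenobiotic genes, 5 and 1 fatty acid synthesis genes and 10 and 0 mitochondrial genes, and with quantile normalization 7 mitochondrial genes. Rescaling to the same sum took the mean to 0.69 for the urea cycle, 0.68 for xenobiotic metabolism and 0.63 for fatty acid synthesis. The genes called lower with that rescaling numbered 18 for TLR4 and NF-kB, 14 for focal adhesion, 13 for acute phase, 14 for crosslinking and 10 each for monocytes and neutrophils and for immediate early genes. Rescaling to the same FPKM sum ended the calls of acute phase (0.0619), crosslinking (0.0609), TGF-β (0.0619), monocyte and neutrophil (0.0609) and immediate early genes (0.139). In the joint model the crosslinking (0.0721), TGF-β (0.0702), monocyte and neutrophil (0.0883) and immediate early (0.0733) calls were lost, with quantile normalization crosslinking and TGF-β (0.0543 each), and at a mean of 5 FPKM monocytes and neutrophils (0.115). Without control replicate 4 the camera adjusted p was 0.164 for crosslinking, 0.110 for TGF-β and 0.106 for immediate early genes. Without knockdown replicate 3 it was 0.288 for TGF-β and 0.192 for immediate early genes (mean −0.59), and without knockdown replicate 4 it was 0.0615 for acute phase. The mitochondrial, bile acid, urea, xenobiotic, TLR4 and focal adhesion lists stayed past the threshold under every scaling and without any 1 library. Camera called 13 lists with the preset correlation and 0 with an estimated one, and fry called 3 (acute phase, adjusted p = 0.0110, urea cycle, 0.0110, and mitochondrial, 0.0498).

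**Figure D2:**
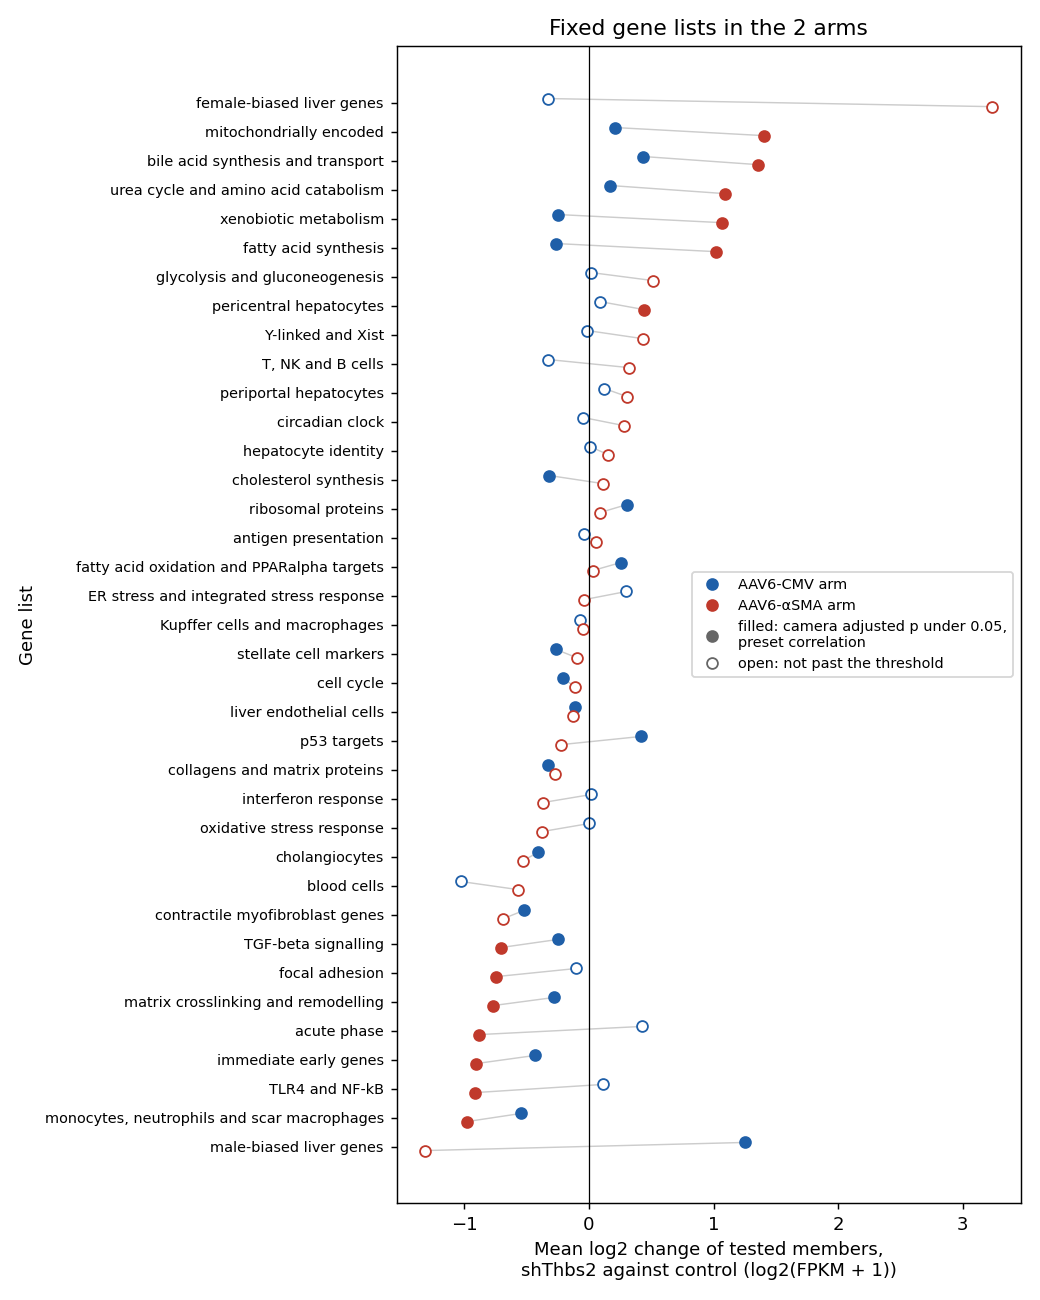
Mean log2 change of fixed lists, knockdown minus control, in the CMV and αSMA arms (2 libraries per group), with filled points where the list passed camera with the preset correlation. Only lists with at least 3 tested members in both arms are drawn, which leaves out the thrombospondins. The mitochondrial list sits at 0.21 in the CMV arm and 1.41 in the αSMA arm, and male-biased genes at 1.25 and −1.32.

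Called genes were also found in the fibrosis lists that did not pass camera in the αSMA arm. Over all 13012 genes limma called 4691, 1729 higher and 2962 lower. Of the collagens and matrix proteins and of the stellate cell markers, a smaller share was called lower than of all genes. Of 12 contractile genes 0 rose and 7 fell by both counts, with a mean of −0.69 (camera adjusted p = 0.0574), among them S100a6 (−2.59, limma adjusted p = 0.00563) and Tpm1 (−0.96, 0.0149). Of 26 collagens and matrix proteins 1 rose and 5 fell, and 0 and 3 adjusted over the list alone, with a mean of −0.28 (camera adjusted p = 0.439). With rescaling to the same FPKM sum 0 rose and 14 fell (mean −0.61), and with median centring 2 rose and 3 fell (mean −0.06). Fibronectin (Fn1, −1.08, limma adjusted p = 0.0122) and tenascin C (Tnc, −1.31, 0.0142) fell. Of 17 stellate cell markers 1 rose and 3 fell, the latter including Cygb (−0.76, limma adjusted p = 0.0277) and the growth factor Hgf (−0.69, 0.0440), and 0 passed adjusted over the list alone. The stellate mean of −0.10 (camera adjusted p = 0.986) changed its sign with the scaling, with 0 higher and 7 lower calls after rescaling to the same FPKM sum and 3 and 1 after median centring.

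Other liver cell lists were mixed in the αSMA arm. Kupffer cell genes (1 rose, 2 fell by both counts, mean −0.05, camera up, adjusted p = 0.714) held Cd68 (−1.69, limma adjusted p = 0.00644) and Clec4f (1.14, 0.0191). Of 10 T, NK and B cell genes 2 rose, Nkg7 (0.80, limma adjusted p = 0.0236) and Igkc (1.44, 0.0361), and 1 adjusted over the list alone (mean 0.32, camera adjusted p = 0.235). Of 15 endothelial genes 2 fell, Plvap (−0.66, limma adjusted p = 0.0376) and Pecam1 (−0.63, 0.0491), and 0 adjusted over the list alone (mean −0.13, camera adjusted p = 0.971). Among 8 cholangiocyte genes Sox9 fell (−2.32, limma adjusted p = 0.00847; mean −0.53, camera adjusted p = 0.403). Hepatocyte identity genes (3 rose, 2 fell by both counts) had a mean of 0.15 and a median of −0.14 (camera adjusted p = 0.437), with Apoa2 higher (1.46, limma adjusted p = 0.0239) and fibrinogen Fgb lower (−1.43, 0.0130). Periportal genes (5 rose, 4 fell by both counts, mean 0.31, camera adjusted p = 0.248) held G6pc, glucose-6-phosphatase (3.47, limma adjusted p = 0.00253), and Cdh1, E-cadherin (−2.31, 0.00563). The means of the Kupffer, endothelial, hepatocyte identity and periportal lists changed sign with the scaling. With rescaling to the same FPKM sum 2 hepatocyte identity genes rose and 10 fell, against 4 and 6 periportal, 1 and 7 Kupffer, 0 and 6 endothelial, 0 and 4 cholangiocyte and 1 and 2 T, NK and B cell genes.

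Further metabolic and stress lists of the αSMA arm held calls in both directions. Of 16 glycolysis and gluconeogenesis genes 7 rose and 5 fell by both counts (mean 0.52, camera adjusted p = 0.235), with Pkm (−1.89, limma adjusted p = 0.00591) and Pfkl (−1.34, 0.00648) lower. Of 22 cholesterol genes 3 rose and 3 fell, and 3 and 2 adjusted over the list alone (mean 0.11, camera adjusted p = 0.301), with Hmgcs1 higher (1.74, limma adjusted p = 0.0112). Of 24 fatty acid oxidation genes 3 rose and 4 fell by both counts (mean 0.03, median −0.12, camera adjusted p = 0.566), with Angptl4 higher (0.93, limma adjusted p = 0.0161) and the coactivator Ppargc1a lower (−1.51, 0.00881). Of 13 oxidative stress genes 2 rose and 5 fell by both counts (mean −0.38, median 0.07, camera adjusted p = 0.986), with Txnrd1 lower (−2.10, limma adjusted p = 0.00563) and catalase higher (Cat, 1.12, 0.0139). ER stress genes (3 rose and 2 fell, 2 and 2 adjusted over the list alone, mean −0.04, median 0.02, camera up, adjusted p = 0.588) held Chac1 (−2.64, limma adjusted p = 0.00591) and Trib3 (2.03, 0.0132). Of 14 cell cycle genes 3 rose and 4 fell by both counts (mean −0.11, camera up, adjusted p = 0.986), with Rrm2 at 1.01 (limma adjusted p = 0.0126) and Mcm6 at −1.19 (0.0208). Of 13 p53 targets 2 fell, Eda2r (−1.18, limma adjusted p = 0.0183) and Zmat3 (−0.64, 0.0384), and 1 adjusted over the list alone (mean −0.22, camera adjusted p = 0.640). Circadian genes (3 rose, 3 fell by both counts, mean 0.28, camera adjusted p = 0.249) held Per1 (−0.94, limma adjusted p = 0.0111). The mean of all of these but glycolysis, oxidative stress and p53 targets changed sign with the scaling. After rescaling to the same FPKM sum 2 cholesterol genes rose and 9 fell, against 3 and 8 fatty acid oxidation, 5 and 5 glycolysis, 1 and 5 oxidative stress, 1 and 7 ER stress, 1 and 7 cell cycle, 0 and 6 p53 target and 2 and 4 circadian genes.

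Of 26 interferon response genes 1 rose and 10 fell by both counts in the αSMA arm (mean −0.37, camera adjusted p = 0.154), with Ifit3 (−1.07, limma adjusted p = 0.00881) and Zbp1 (−1.09, 0.0135) lower. Of 13 antigen presentation genes Tap1 fell (−0.78, limma adjusted p = 0.0204; mean 0.06, camera adjusted p = 0.403). Of 11 male-biased genes 2 fell, Mup3 (−1.88, limma adjusted p = 0.0165) and Cyp4a12b (−2.22, 0.0357), and 1 adjusted over the list alone (mean −1.32, camera adjusted p = 0.235). Of 4 female-biased genes Cyp2a4 and Cyp2b9 rose by both counts (mean 3.24, camera adjusted p = 0.102), and that list passed with rescaling to the same FPKM sum (0.0124; adjusted p = 0.879 with an estimated correlation). Both genes are also members of the xenobiotic list. Among Y-linked genes Uty rose (0.93, limma adjusted p = 0.0146), and 2 rose adjusted over the list alone (mean 0.43, camera adjusted p = 0.235). Ribosomal protein genes (mean 0.09, camera adjusted p = 0.132) held 1 gene that rose by limma, and 0 adjusted over the list alone. Blood cell genes (mean −0.57, camera adjusted p = 0.566) and adipose and mesothelium genes (−0.44, 0.588) held 0 calls by limma. After rescaling to the same FPKM sum 0 interferon response genes rose and 15 fell, against 0 and 3 antigen presentation, 0 and 4 male-biased and 0 and 5 ribosomal genes. The antigen presentation and ribosomal means changed sign with the scaling, and median centring brought the contractile (0.0353) and ribosomal (0.0394) lists past the threshold, as did quantile normalization the contractile list (0.0486). With an estimated correlation the adjusted p was 0.896 for both lists with median centring and 0.890 for the contractile list with quantile normalization.

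The last comparison asks whether the hairpin effect was alike in both arms, which differ in vector, platform and provider together. Angptl4 was the only gene called in both, where 0.244 would be by chance, and its rise of 2.01 in the CMV arm and 0.93 in the αSMA arm differed by −1.09 (SE 0.21, limma adjusted p = 0.0105). Across the 10245 genes tested in both arms the log2 changes correlated with r = 0.154 and rho = 0.232, and genes are not independent replicates. Of 3756 αSMA-called genes 2294 (61.1%, against 50% by chance) had the same sign in the CMV arm. Of 413 genes called in the αSMA arm with an unadjusted p under 0.05 in the CMV arm, 159 were higher in both (68.4 by chance) and 150 lower in both (107 by chance). In opposite directions, 68 were higher in the CMV arm alone (137 by chance) and 36 in the αSMA arm alone (53.5 by chance).

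The limma test of the difference called 2571 genes, 790 with a higher and 1781 with a lower effect in the αSMA arm. The smallest adjusted p belonged to Gstm2, a glutathione transferase with close paralogs (−0.92 in the CMV arm, 3.02 in the αSMA arm, difference 3.94, adjusted p = 0.000382), and Plscr2 (0.31, 3.67, difference 3.36, adjusted p = 0.000382). They were followed by the transporter Slc17a4 (difference 3.38, adjusted p = 0.000651), Gclc (−3.35, 0.000651), Serinc5 (−3.0, 0.000691), the mitochondrial peptide Mtln (2.48, 0.000922), Gstm4 (2.91, 0.000922) and the permeability pore regulator Ppif (−2.50, 0.00124). The number was 745 without αSMA control replicate 4, 900 without CMV knockdown replicate 2, 1092 without CMV knockdown replicate 1, 1378 without αSMA control replicate 3, 1533 without CMV control replicate 1 and 1635 without αSMA knockdown replicate 3.

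**Figure D3:**
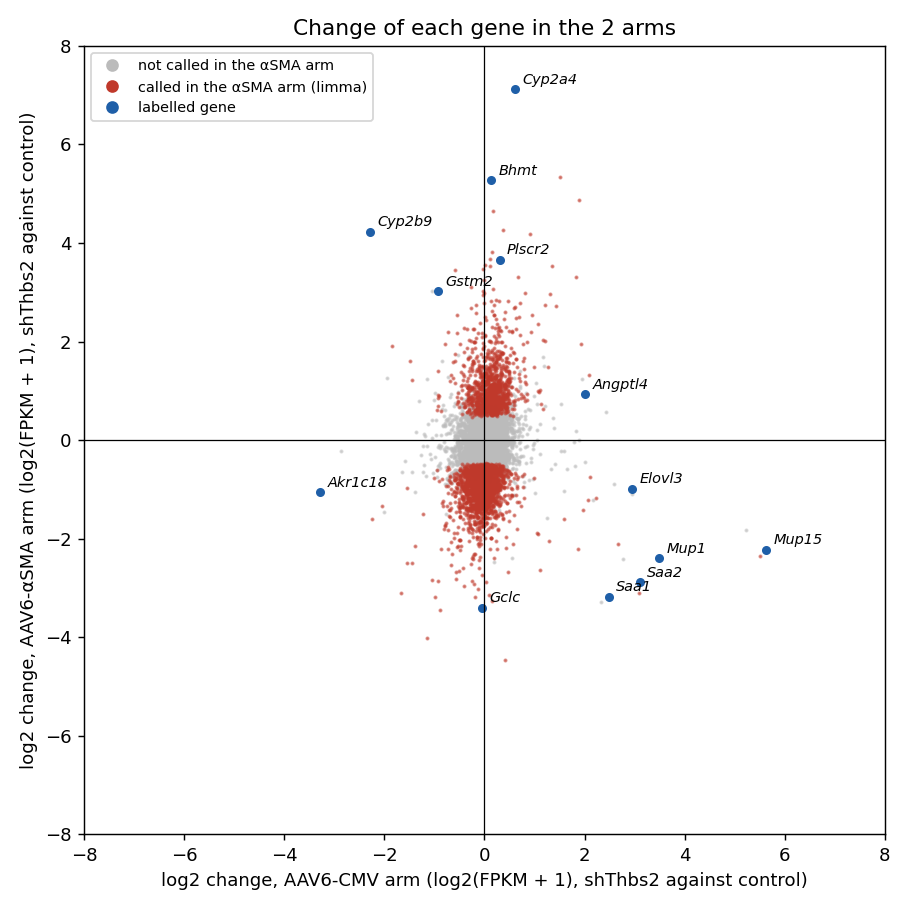
Log2 change (knockdown minus control) of each of the 10245 genes tested in both arms, CMV arm on the x axis and αSMA arm on the y axis (2 libraries per group), with red points for genes called in the αSMA arm and names for some of the genes in the text. Angptl4 lies at 2.01 and 0.93, and the correlation across genes is r = 0.154.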

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

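The tests of the mitochondrial share, of the same change in both arms, of the respiratory chain by camera and by scaling, of the length and GC trends singly, of nuclear copies, of mixed sex and of Mup paralogs were chosen after the results were seen. Each value in the next 4 paragraphs is the effect in the αSMA arm minus that in the CMV arm on the log2 scale, and each was picked out because the limma test of that difference passed for named genes (adjusted p from 0.000382 to 0.0453) or camera with the preset correlation for lists. Vector, platform and provider differ together between the arms, so none of them can be told apart as the source.

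The difference was −1.03 for Tgfb1, −0.72 for its receptor Tgfbr2, −1.60 for Adamts1, −2.71 for Vcl and −1.10 for Actn1. It was −2.45 for Ccl2, −1.93 for Chil3, −5.66 for Saa1, −5.99 for Saa2 and −2.61 for Ier3. It was higher for the matrix genes Postn (1.05) and Pcolce (1.18).

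Steroid, bile acid and aldo-keto reductase genes differed by 3.42 (Cyp7a1), 3.22 (Cyp17a1), 2.22 (Akr1c18), 3.55 (Akr1b7), 1.65 (Slco1b2) and 3.26 (Serpina6), and Serpina7, which encodes the thyroid hormone carrier of plasma, by 1.48. Lipid genes differed by 4.48 (Thrsp), 1.97 (Acaca), 1.26 (Srebf1), 1.95 (Pnpla3), 1.47 (Dhcr7), 2.1 (Lpl), −0.91 (Dgat2), −3.93 (Elovl3) and −1.09 (Angptl4). Amino acid and nucleoside genes differed by 2.1 (Cth), 5.15 (Bhmt) and 3.83 (Upp2). Glutathione transferases and other cytochrome P450 genes differed by 3.94 (Gstm2), 3.76 (Gstm3), 2.15 (Cyp2b10), 6.52 (Cyp2b9), 6.51 (Cyp2a4), 3.90 (Cyp2a22) and −4.09 (Cyp4a12b), families with close paralogs. The hepcidin regulator Hjv, listed as Hfe2 in the CMV table, differed by 3.57 and Hamp2 by 3.67.

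Stress and other genes differed by −3.35 (Gclc), −2.07 (Cdkn1a), −1.39 (Herpud1), −2.25 (Hspb1), −4.87 (Sprr1a), −3.40 (Slc30a4), −2.54 (Abhd2) and 3.36 (Plscr2). The mitochondrial genes mt-Atp6 (1.71), mt-Nd3 (1.25) and mt-Nd4 (0.97) had the higher effect in the αSMA arm. Rps27 differed by −1.90, Mup1 by −5.88 and Mup15 by −7.86, with Mup reads shared among near-identical genes.

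Among lists the mean difference was 1.20 for mitochondrially encoded genes (camera adjusted p = 5.36e-09), 0.92 for bile acids (6.75e-06), 0.92 for the urea cycle and amino acids (6.75e-06), 1.28 for fatty acid synthesis (1.95e-05), 1.27 for xenobiotic metabolism (0.000166), 0.43 for cholesterol synthesis (0.00692), 0.36 for pericentral hepatocytes (0.0228) and 4.48 for female-biased genes (0.0228). It was −0.92 for TLR4 and NF-kB (0.00353), −1.30 for acute phase (0.00956), −2.63 for male-biased genes (0.0130) and −0.66 for focal adhesion (0.0453). The female-biased list had 3 genes tested here. Cyp2a4 (6.51) and Cyp2b9 (6.52) are members of both the female-biased and the xenobiotic list, so these results overlap. The median of the xenobiotic list was 0.54. With an estimated correlation the lowest camera adjusted p of any list was 0.446, so none of the 12 lists above passed. Fry passed for the mitochondrial (adjusted p = 0.0128), acute phase (0.0160), TLR4 (0.0233), urea cycle (0.0233), bile acid (0.0301) and focal adhesion (0.0434) lists. It also passed for oxidative stress (mean −0.49, 0.0276), which did not pass camera (0.668). The fatty acid synthesis, xenobiotic, cholesterol, pericentral, female-biased and male-biased lists did not pass fry. With the preset correlation the collagen (0.10, camera adjusted p = 0.193), stellate cell (0.19, 0.138), crosslinking (−0.42, 0.468), TGF-β (−0.59, 0.243), fatty acid oxidation (−0.23, 0.956) and glycolysis lists (0.56, 0.166) were among those that did not pass.

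The αSMA arm had 4691 genes past the limma threshold and the CMV arm 2. Removing each αSMA library's trend on transcript length and GC content left 4271 calls (2135 higher, 2136 lower), so these trends do not account for the whole difference. Rescaling over nuclear protein-coding genes left 4283 calls. It moved the median log2 change of all αSMA genes only from −0.165 to −0.173, so the nuclear protein-coding sums hardly differed between the groups. A correction this small cannot test other effects of the mitochondrial share. The same change in both arms is argued against by the test of the difference over all 10245 genes tested in both, which 25.1% passed (2571 genes, and 745 without αSMA control replicate 4), with 4177 at an unadjusted p under 0.05, where 512 would be by chance. A difference between the vectors, between the platforms and providers, or between animals that happened to form the groups stays open and could not be tested with 2 libraries per group. The count fell to 46 without control replicate 4.

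Transcripts of the mitochondrial genome rose in the αSMA arm by a median of 1.32 (quartiles 1.09 to 1.77). With the length trend removed the median was 1.26 (quartiles 0.97 to 1.43), with the GC trend removed 1.16 and with both removed 0.76 (quartiles 0.70 to 1.01, 8 of 13 genes past the threshold), so a preference for short transcripts is not the whole cause. Reads moved between these genes and their 7 nuclear copies on chromosome 1 would leave the summed FPKM unchanged, but that sum rose by 1.36, from between 184240 and 196453 to between 483749 and 495406. A rise of the respiratory chain as a whole stays open, since the median of its 51 nuclear-encoded genes lay 0.53 above that of all genes but 0.45 with rescaling to the same FPKM sum and 0.36 with quantile normalization, against a limit of 0.5, and camera passed with the preset correlation (p = 5.53e-08) but not with an estimated one (p = 0.396). The mitochondrial ribosomal RNAs mt-Rnr1 (−0.40, limma adjusted p = 0.223) and mt-Rnr2 (−0.30, adjusted p = 0.397) did not pass.

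Male-biased liver genes had a mean change of 1.25 in the CMV arm (camera adjusted p = 3.16e-08; adjusted p = 0.379 with an estimated correlation) and of −1.32 in the αSMA arm, where the list did not pass (adjusted p = 0.235) and 2 of 11 genes fell by limma. The difference between arms passed camera with the preset correlation (adjusted p = 0.0130) and not with an estimated one (adjusted p = 0.798). Animals of mixed sex are argued against by Eif2s3y, a Y-linked gene, at 22.0 FPKM or more in all 8 libraries, and by Xist at 0 to 0.02 FPKM in the αSMA libraries. Reads shared among Mup paralogs do not account for the pattern, since outside that family the median was 1.26 in the CMV arm (9 of 9 genes higher, quartiles 0.51 to 1.59) and −1.04 in the αSMA arm (0 of 8 higher, quartiles −1.74 to −0.74). The male-biased genes vary together, with an estimated correlation of 0.62 in the CMV arm and 0.91 in the αSMA arm. The counts of genes are therefore not independent. Cyp4a12b measured 6.78 and 22.1 FPKM in the αSMA controls and 2.91 and 1.12 FPKM in the knockdown. A difference in hormonal state between groups of animals is a candidate explanation that was not tested. Vector, platform, provider and animals that happened to form the groups stay open too.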

How the results depend on the processing

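Rescaling over nuclear protein-coding genes, testing protein-coding genes alone and the settings of the respiratory chain and mitochondrial genes were chosen after the data were seen. The number of genes past the limma threshold in the CMV arm, 2, became 0 without a filter on low values (limma; 1113 at an unadjusted p under 0.05 with the filter), 5 with rescaling over nuclear genes, 118 with a threshold on unadjusted p and a 2-fold change, and 10 to 152 with 1 library left out. In the αSMA arm 4691 became 1843 without a filter, 2070 with the unadjusted threshold, and 46 to 4137 with 1 library left out. The lists called by camera, 20 in the CMV arm and 13 in the αSMA arm, became 0 and 0 with an estimated correlation, which tests on the few residual degrees of freedom. They became 0 and 3 with fry, which tests another question. The genes whose effect differed between arms, 2571, became 1659 at a mean of at least 5 FPKM, where fewer genes are tested, 4272 with rescaling to the same FPKM sum, and 745 to 3183 with 1 library left out. The correlation between arms, 0.154, became 0.119 with quantile normalization and 0.107 to 0.185 with 1 library left out. The median of the nuclear respiratory chain genes, 0.36 in the αSMA arm, became −0.045 with rescaling to the same FPKM sum. The cause of the other shifts was not tested.

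Libraries with the same replicate number shared little deviation from their group means, with a correlation across genes of 0.040 in the CMV arm and 0.0013 in the αSMA arm. Whether the numbers mark pairs is not given in the labels, and 2 libraries per group cannot settle it. With a replicate block the CMV arm had 17 genes, the αSMA arm 4317, and 2224 differed between arms. Thbs2 stayed lower and short of the threshold in both arms under every alternative, with a log2 change of −0.06 in the αSMA arm under median centring and an adjusted p of 0.0703 there with rescaling to the same FPKM sum. A mean of at least 5 FPKM gives no value for Thbs2. Over the genes picked by the rules and the called lists 0 changed direction past the threshold. Of the results for single αSMA genes, 506 kept their side of the threshold under the other settings, 22 lost it and 9 gained it, and with 1 library left out 111 kept it and 109 lost it. For CMV genes these were 559, 3 and 11, and with 1 library left out 168 kept it and 68 gained it. Read depth is unknown, so what it limits cannot be given.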

Other observations

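The nuclear-copy test, the camera test and settings of the respiratory chain and the choice of Gm28661 and Gm28438 below were made after the results were seen. Of 51 nuclear-encoded respiratory chain genes in the αSMA arm, 18 rose, 0 fell and 33 did not pass limma, with a median of 0.36 (quartiles 0.19 to 0.76) against −0.16 for all genes. Camera on this list alone gave p = 5.53e-08 with the preset correlation and p = 0.396 with an estimated one. With rescaling to the same FPKM sum the median was −0.045 against −0.50 for all genes, and 7 rose and 4 fell. Limma called 0 of the 51 without control replicate 3 or control replicate 4, and 4 without knockdown replicate 3. On chromosome 1, between 24611535 and 24616197 on the minus strand, the αSMA table lists 7 unprocessed pseudogenes that are copies of mitochondrial genes. Their summed FPKM was 82091 ± 6926 in the controls and 198821 ± 1184 in the knockdown (SD, n = 2), a log2 ratio of 1.28. Among them Gm28661 measured 22395 and 56580 FPKM and Gm28438 13235 and 48772 FPKM. Between 97.2% and 100% of the 30-base words of these copies occur in the mitochondrial transcripts, so their reads cannot be assigned to either place. The CMV table lists 0 of them. Processed, unprocessed and transcribed unprocessed pseudogenes, these 7 copies included, made up 11.1% and 10.1% of the FPKM sum in the αSMA controls and 17.6% and 18.0% in the knockdown.

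Both pancreatic elastase genes abundant enough to test rose in the αSMA arm, Cela2a by 1.89 (0.395 to 4.24 FPKM, limma adjusted p = 0.00816) and Cela1 by 1.36 (11.6 to 31.3 FPKM, adjusted p = 0.00847). The skeletal muscle gene Mylpf had a change of −0.21 (adjusted p = 0.633). The 10 most abundant genes took 23.8% and 23.0% of the FPKM sum in the αSMA controls and 35.5% and 36.8% in the knockdown. In the CMV table, which lists other features, they took 25.1% and 25.5% in the controls and 21.9% and 22.6% in the knockdown. Albumin (Alb) had a log2 change of −0.53 in the CMV arm, where the means were 49943 and 34499 FPKM (limma adjusted p = 0.230), and of −0.10 in the αSMA arm.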
